A study of Homo sapiens with 4 samples.

How the data were processed

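Gene expression was measured in U937 cells, an established human line of immature monocyte-like blood cells, on Affymetrix Human Genome U133 Plus 2.0 arrays. The 4 arrays fell into 4 groups of 1 array each: untreated control cells, cells given Sonazoid at 0.05%, cells given 1 min of ultrasound (intensity 0.3 W/cm2), and cells given both. Sonazoid is an ultrasound contrast agent of gas-filled microbubbles. The treated cells were incubated for 3 h before collection; whether the control cells were kept for the same time is not given in the sources used here. Per the labels' protocols, total RNA was treated with DNase and biotin-labelled RNA was made with the manufacturer's one-cycle kit for amplification from the 3' end. Groups were taken from the treatment label of each sample.

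The deposited values are linear intensity values, 1 per probe set and array, from 0.0486 to 21728. The summarisation algorithm, its version, any scaling target of the authors and the detection calls are not given in the sources used here. The trimmed means of the deposited arrays, with 2% of the values removed at each end, differed 1.16-fold between the highest and the lowest array. A rule written before the data were examined called for scaling above a 1.1-fold difference, so each array was multiplied by 1 factor to reach the common trimmed mean. The factors were 1.04 for control, 0.977 for Sonazoid only, 1.07 for ultrasound only and 0.923 for the combination. Values under the median of all scaled values of the 4 arrays (23.8, the floor) were then set to it, and log2 was taken. A difference with 1 side at the floor is a lower bound, is written as "at least", and was not ranked with the others.

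Of the 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 had none. Symbols were updated through Entrez identifiers with the RefSeq gene table of assembly GRCh38.p14 for 41043 probe sets, and no coordinates were used. Probe sets with several symbols or none were left out, and so were the 62 control probe sets of the array. Each of the 19775 genes was represented by its brightest probe set by mean signal, and 13965 genes lay above the floor on at least 1 array. The genes above the floor numbered 12018 on the control array, 11984 with Sonazoid only, 12252 with ultrasound only and 12093 with the combination. No member of the lists below that is missing from the table is reported; HSPA1A, HSPA1B and BTG2 were among these, because no probe set with their symbol alone was on the table.

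There were no replicates, so no test between groups was made and no p-value or standard error is given. With 1 array per group the number of arrays limits the precision. A gene counted as higher or lower at 2-fold or more, a log2 difference of 1. The 5 comparisons were the combination against control, ultrasound only against control, Sonazoid only against control, the combination against ultrasound only, and the combination against Sonazoid only. The departure from additivity was the log2 difference of the combination from Sonazoid only minus that of ultrasound only from control. The combination against Sonazoid only and ultrasound only against control share no array, and neither do the combination against ultrasound only and Sonazoid only against control. Overlaps and correlations across genes were therefore taken within these pairs. The overlap expected of independent lists was the product of the 2 counts divided by the genes measured in both. Shares of genes have exact Clopper-Pearson 95% intervals, which cover counting error only and treat genes as independent, which they are not.

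The genes named were fixed by a rule. For the combination against control they were the 12 genes with the largest positive and the 12 with the largest negative log2 difference, among genes above the floor on both arrays with no other above-floor probe set going the opposite way, and then the 4 largest lower bounds each way. For the other comparisons and the departure they were the 5 largest each way. Up to 4 measured members of each gene list, those farthest from 0 in the combination against control, and ACTB and GAPDH as control genes were also named. Genes named outside this rule are marked as chosen after their values were seen.

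The gene lists fixed in advance covered immediate early genes, MAPK phosphatases and ERK feedback, short-lived regulatory transcripts, heat shock proteins and co-chaperones, the unfolded protein response, the ATF4 and amino acid response, NRF2 and oxidative stress, metallothioneins and zinc response, p53 targets, NF-kB targets and inflammatory cytokines, interferon-stimulated genes, pro-apoptotic and death receptor genes, anti-apoptotic genes, SRF and actin cytoskeleton targets, membrane repair with annexins and mechanosensitive channels, hypoxia and glycolysis, cholesterol synthesis, G1/S and DNA replication, G2/M and mitosis, histones, ribosomal proteins, nuclear-encoded oxidative phosphorylation, lysosome and autophagy, monocyte and macrophage differentiation, and myeloid progenitor markers. A further 5 lists held markers of T and NK cells, B cells, erythroid cells and platelets, epithelial cells, and fibroblasts and endothelial cells. Each list's median log2 difference was set beside the central 95% of 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these arrays. Of 30 lists, 1.5 would be expected outside this range by chance in each comparison if genes were independent, which they are not. Some lists also share members, such as FOS and KLF6, so the number of lists outside cannot be weighed against 1.5. The ranges were computed with the main processing only and not anew for the alternatives below.

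The control probe sets were used for RNA quality, as 3' to 5' signal ratios, and for spike-in controls. Other above-floor probe sets of a counted gene were checked for a difference of at least 1.5-fold the same way. Alternatives planned before the data were examined were scaling to equal medians, quantile normalisation, floors at the 40th and 60th percentiles, a pseudocount in place of the floor, the mean of all probe sets of a gene, gene-specific probe sets without the suffixes that mark shared ones, and thresholds of 1.5-fold and 3-fold. A floor at the 75th percentile (151) and the values as deposited were added after seeing the data. Genes with a mean signal under 151 are called dim.

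The counting was tested on simulated arrays made from the geometric mean of the 4 arrays, with noise drawn from the differences between the Sonazoid only and control arrays at similar signal. Known differences were put into 200 genes well above the floor, and 13215 genes were measured in the simulated combination against control. At a simulated 3-fold difference 50 of 50 genes were counted each way, and at 2-fold 33 of 50 higher and 25 of 50 lower. Of 13015 unchanged genes 479 were counted, more than were counted on the real arrays, so the simulated noise was larger than the measured one. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.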

Results

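The data were the signals of 19775 genes in U937 cells on 4 arrays, 1 each for untreated cells, Sonazoid only, ultrasound only and the combination of both. The median deposited signal was 22.6 for control, 23.8 for Sonazoid only, 22.6 for ultrasound only and 26.4 for the combination. The 3' to 5' signal ratio of ACTB, a measure of RNA integrity, was between 1.16 and 1.20 on the 4 arrays, and that of GAPDH between 0.946 and 1.01, both from probe sets near the top of the signal range. That of ISGF3A, a weaker control, was 6.47 in control, 7.52 with Sonazoid only, 9.21 with ultrasound only and 7.09 in the combination. Each difference below is between single arrays. Signals are scaled probe set intensities.

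The combination against control addresses the question in the title of the series, which genes respond to Sonazoid together with ultrasound. The 45S precursor of ribosomal RNA (RNA45SN5) was 10.8-fold higher, and HSPA6, a strictly stress-inducible HSP70 chaperone, was 8.67-fold higher, with signals of 97.3 in control and 844 in the combination. The zinc finger transcription factors KLF6 and KLF4 were 7.47-fold and 4.59-fold higher. TRIB1, a pseudokinase that directs C/EBP alpha to degradation, was 6.80-fold higher, TSC22D3, the glucocorticoid-induced leucine zipper protein, 6.28-fold, and RGS2, which switches off G protein signals, 6.08-fold. With ultrasound only KLF6 was 7.18-fold, TSC22D3 6.67-fold and RGS2 5.93-fold above control, close to the combination, while TRIB1 (4.11-fold) stood lower than in the combination. KLF4 was 3.48-fold above control with ultrasound only, and its other probe set differed little between the arrays with ultrasound (log2 2.18 and 2.24 over control).

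Other genes named at the top were IFIT1, an interferon-induced RNA-binding protein (5.04-fold higher), the AP-1 subunit FOS (4.69-fold), FCAR, the myeloid receptor for IgA (4.22-fold), EMP1, a tetraspan membrane protein (4.13-fold), and MATCAP2, of a family of tubulin-trimming proteases (3.84-fold). FOSB, another AP-1 subunit, was below the floor in control and at 307 in the combination, at least 12.9-fold higher. IFIT2 was at least 5.55-fold higher, the beta-defensin DEFB124 at least 4.36-fold and the calcium-binding protein S100A2 at least 3.64-fold. Other above-floor probe sets had log2 differences of 3.51 for RNA45SN5 (3.43 for the brightest), 3.26 for HSPA6 (3.12), 2.11 for TSC22D3 (2.65), 2.24 for KLF4 (2.20) and at least 2.16 for EMP1 (2.04). The 4 others of KLF6 ranged from at least 0.86 to 3.08 (2.90) and the 4 of FCAR from 0.41 to 1.97 (2.08), with 1 of FCAR a lower bound (at least 0.81).

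**Figure D1:**
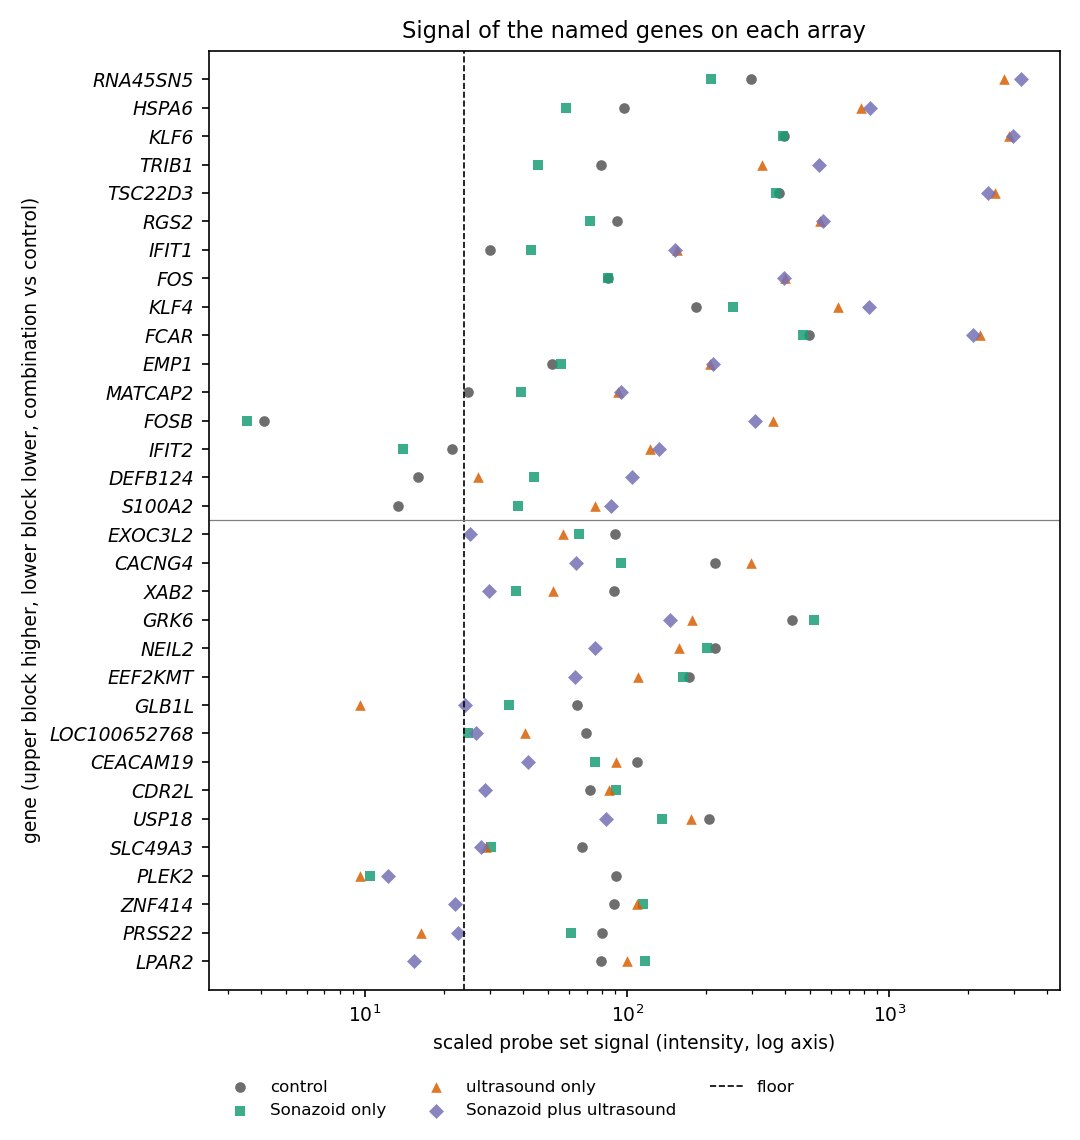
Scaled probe set signal (log axis) of the named genes of the combination against control, with 1 point per array and the floor of 23.8 as a dashed line. In the upper block the ultrasound only and combination points lie together for most genes, as for KLF6 at 2852 and 2968 against 397 in control. The lower block holds genes lower in the combination, such as GRK6 at 145 against 427 in control.

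Immediate early genes, transcribed within minutes to hours of a stimulus, were the list farthest from 0. The median of its 25 measured members was 0.91 (log2), where random lists ranged from -0.13 to 0.12, and 12 members were at least 2-fold higher and 0 at least 2-fold lower. FOSB, KLF6, KLF2 (at least 5.19-fold) and FOS were the most different members. KLF2 rested on 1 probe set that was at 5.8 in control and 124 in the combination; its gene-specific probe set had a log2 difference of -0.15. Of 21 short-lived regulatory transcripts 4 were at least 2-fold higher, with a list median of 0.25 against a random range of -0.11 to 0.11, and of 0.75 with gene-specific probe sets. Among them were JUN, the AP-1 partner of FOS (2.64-fold), and MCL1, an unstable anti-apoptotic protein of the BCL2 family (2.28-fold, signals of 2085 and 4762). The MAPK phosphatases and ERK feedback list had a median of 0.10 over 17 members, inside the random range, and 4 members were at least 2-fold higher. They were PHLDA1 (5.77-fold), DUSP1, a phosphatase that inactivates p38 and JNK (3.65-fold), DUSP10 (2.18-fold) and IER3 (2.04-fold). PHLDA1 was kept out of the ranked genes above because another above-floor probe set of it went the opposite way.

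Of 18 heat shock proteins and co-chaperones 1, HSPA6, was at least 2-fold higher and the list median was 0.07; the co-chaperone BAG3 was 1.57-fold higher, DNAJB1 1.41-fold and HSPA1L 1.36-fold. The ATF4 and amino acid response list had a median of 0.09 over 19 members. Its members PPP1R15A, which restarts translation by recruiting a phosphatase to eIF2 alpha, and DDIT4, an inhibitor of mTORC1, were 3.63-fold and 3.10-fold higher, while ATF4 was 1.49-fold and ASNS 1.42-fold higher. In the NRF2 and oxidative stress list (median 0.03, 20 members) the heme-degrading enzyme HMOX1 was 3.36-fold higher, at 758 and 2550, and SOD2 was 2.16-fold higher with a dim signal. SLC7A11 was 1.26-fold higher and MAFG 1.18-fold lower. The unfolded protein response list had a median of 0.07 over 17 members, with CALR 1.22-fold, DNAJB11 1.19-fold and HERPUD1 1.15-fold higher and SDF2L1 1.16-fold lower. The metallothionein list had a median of 0.00 over 7 members, whose sign turned under quantile normalisation. It was 0.78 with gene-specific probe sets, which left SLC30A1 alone, since all measured metallothioneins rest on probe sets that may bind related sequences; the zinc exporter SLC30A1 was 1.71-fold higher, MT2A 1.17-fold and MT1X 1.08-fold higher, and MT1E 1.1-fold lower, but slightly higher with the values as deposited.

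Inflammatory genes were higher as a group. The 19 NF-kB targets and cytokines had a median of 0.29, outside the random range of -0.14 to 0.13, and 15 of them lay above 0. The chemokine CXCL2 was 2.44-fold, the inhibitor of NF-kB family member NFKBIZ 2.02-fold, TNF 1.72-fold and NFKB2 1.65-fold higher. Of 17 interferon-stimulated genes 2 (IFIT1 and IFIT2) were at least 2-fold higher, with CXCL10 at 1.95-fold and IFIT3 at 1.87-fold, and the list median was 0.02.

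Genes of cell death showed no common shift. The pro-apoptotic list had a median of -0.01 over 23 members, inside the random range and positive under each other scaling, with 0 members at 2-fold either way. PMAIP1, which encodes the BH3-only protein NOXA, was 1.69-fold and the death receptor FAS 1.43-fold higher, and APAF1 was 1.57-fold and BMF 1.46-fold lower. Among 14 anti-apoptotic genes (median 0.06) MCL1 was the 1 member at 2-fold; BAG3 was 1.57-fold and PIM2 1.35-fold higher and BCL2L1 1.29-fold lower. The 18 p53 targets had a median of 0.06 and 0 members at 2-fold, with PLK3 at 1.98-fold, CDKN1A at 1.73-fold and PMAIP1 at 1.69-fold higher and PHLDA3 1.61-fold lower.

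Cell cycle lists stood near 0. G2/M and mitosis genes had a median of -0.12 over 26 members, below the random range of -0.09 to 0.07, and a median of 0.05 with the values as deposited, where the sign turned. PLK1, a mitotic kinase, was 1.48-fold lower, KIF20A 1.22-fold and HMMR 1.18-fold lower, and CDK1 1.25-fold higher. The G1/S and DNA replication list had a median of -0.01 over 23 members, positive with the values as deposited, with CCNE2 1.40-fold, MCM10 1.22-fold and GINS2 1.19-fold higher and CCND2 1.28-fold lower. Histone genes had a median of 0.31 over 11 members against a random range of -0.20 to 0.22, but of 0.0044 with gene-specific probe sets. H4C8 was 1.92-fold, H3C2 1.61-fold and H2BC12 1.35-fold higher, and H1-4 was 1.39-fold lower. Ribosomal proteins had a median of -0.05 over 21 members, whose sign turned under quantile normalisation and with the values as deposited; RPL3 was 1.14-fold, RPL7 1.1-fold, RPL8 1.09-fold and RPL10A 1.08-fold lower, the last 3 slightly higher with the values as deposited. Nuclear-encoded oxidative phosphorylation genes had a median of 0.01 over 22 members, negative under quantile normalisation, with SDHA 1.19-fold and SDHC 1.14-fold lower and NDUFA1 1.14-fold and COX6A1 1.12-fold higher.

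Annexin A1 (ANXA1), a calcium-dependent phospholipid-binding protein, was 2.98-fold higher at 2013 and 6005, the 1 of 20 membrane repair and channel genes at 2-fold (list median 0.08). PANX1, a membrane channel subunit, was 1.85-fold higher, the mechanosensitive channel PIEZO1 1.24-fold higher and TRPV2 1.54-fold lower. SRF and actin cytoskeleton targets had a median of -0.10 over 14 members, positive with the values as deposited; ZYX was 1.42-fold, TPM4 1.34-fold, CNN2 1.28-fold and MYL9 at least 1.15-fold lower. In the hypoxia and glycolysis list (median -0.03, positive with the values as deposited, 22 members) PFKFB4 was 2.11-fold and ADM 2.07-fold higher, and PFKL and HK1 were each 1.39-fold lower. Cholesterol synthesis genes had a median of -0.02 over 15 members, positive with the values as deposited, with MVD 1.35-fold and STARD4 1.20-fold higher, MVK 1.24-fold and LSS 1.18-fold lower. Lysosome and autophagy genes had a median of 0.00 over 21 members, negative under quantile normalisation, with CTSB 1.20-fold and WIPI1 1.19-fold higher, MCOLN1 1.33-fold and CTSD 1.19-fold lower.

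Monocyte and macrophage differentiation genes had a median of 0.15 over 14 members, inside the random range, and 3 were at least 2-fold higher: CSF1R, the receptor for macrophage colony-stimulating factor (2.41-fold), TREM1 (2.25-fold) and FPR1 (at least 2.14-fold). CD86 was at least 1.68-fold lower. Myeloid progenitor markers had a median of -0.08 over 12 members, positive with the values as deposited; SPI1, the transcription factor PU.1, was 2.03-fold lower with a dim signal, CD4 1.29-fold, CEBPA 1.21-fold and HMGA1 1.20-fold lower. Markers of other cell types were few and mostly near the floor. The T and NK list had a median of -0.18 over 3 members, CD5 (at least 1.28-fold lower), CD7 (at least 1.14-fold lower) and NKG7 (1.09-fold higher, 2920 and 3197). The B cell list had a median of -0.01 over 6, positive with the values as deposited, with BLK at least 2.58-fold and CD22 at least 1.91-fold lower and CD79A 1.18-fold and MS4A1 at least 1.05-fold higher. Of the erythroid and platelet markers HBB was 1.78-fold lower and AHSP at least 1.1-fold higher, with no other measured. The epithelial list had a median of 0.42 over 4 members, inside the random range of -0.46 to 0.54; KRT8 was at least 2.48-fold and CLDN7 at least 1.81-fold higher, MUC1 was 1.30-fold lower, and KRT19 stood at the floor in the combination and at 23.9 in control. The fibroblast and endothelial list had a median of -0.10 over 7, positive with the values as deposited, with THY1 1.80-fold and DCN at least 1.75-fold higher and COL1A2 at least 1.40-fold and COL1A1 1.22-fold lower.

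**Figure D2:**
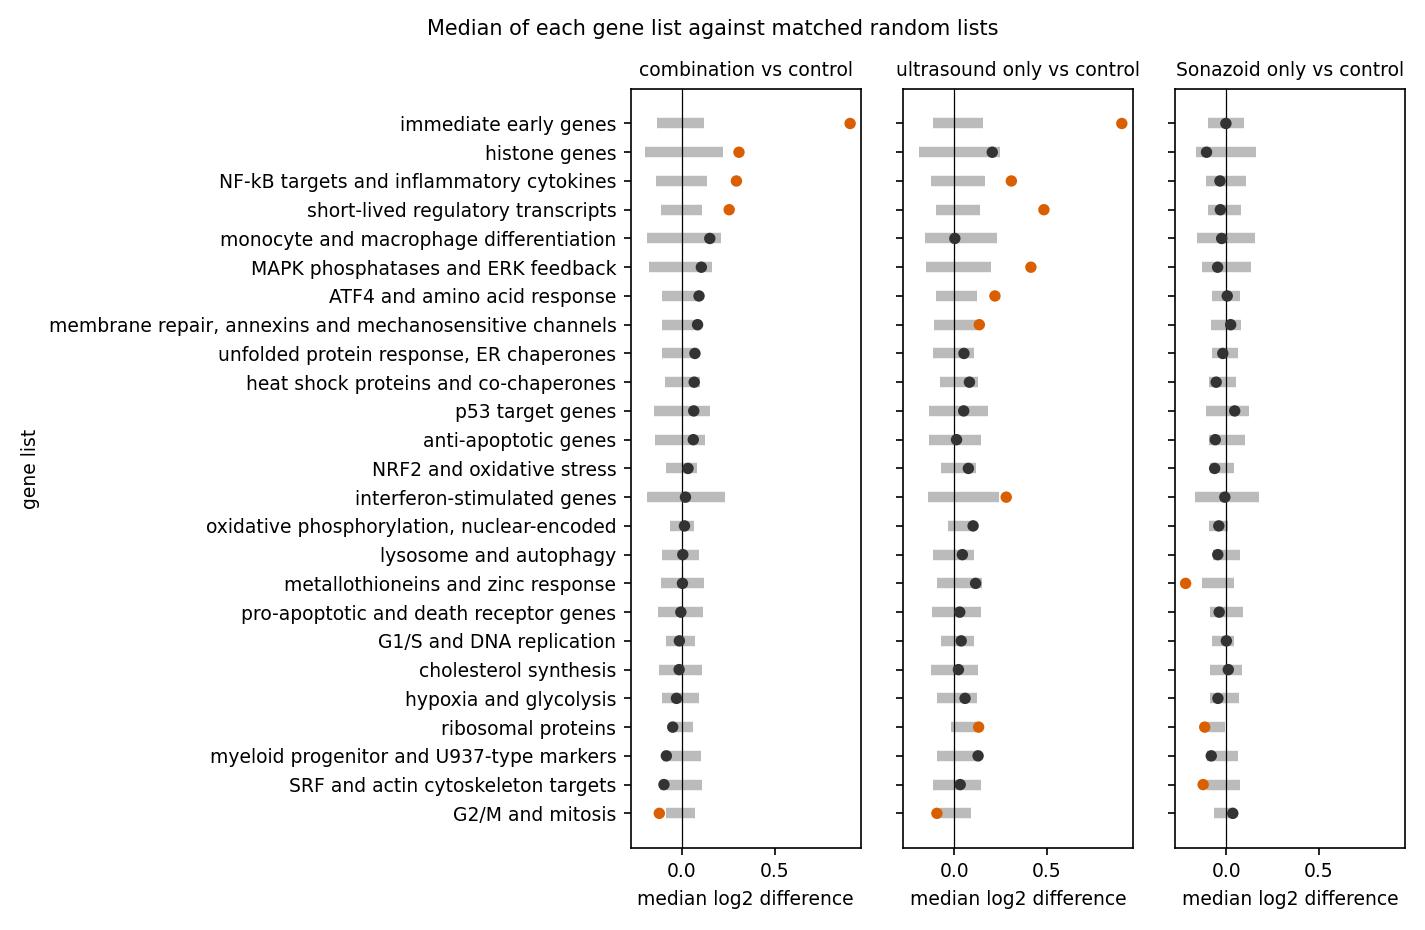
Median log2 difference of each gene list (points, orange where outside the random range) in 3 comparisons against control, with the central 95% of 10000 matched random lists as grey bars. Immediate early genes stand at 0.91 in the combination and 0.90 with ultrasound only, far outside the bars, and at 0.00 with Sonazoid only.

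Genes lower in the combination had weaker signals. EXOC3L2, related to exocyst subunits, was 3.57-fold lower, the calcium channel auxiliary subunit CACNG4 3.37-fold, XAB2, a splicing and DNA repair factor, 3.00-fold, and GRK6, a kinase of G protein-coupled receptors, 2.94-fold (427 and 145). The DNA glycosylase NEIL2 was 2.86-fold lower, EEF2KMT, which methylates elongation factor 2, 2.72-fold, GLB1L 2.67-fold, LOC100652768 2.64-fold, CEACAM19 2.61-fold, CDR2L 2.5-fold, USP18, the protease that removes ISG15, 2.48-fold and SLC49A3 2.44-fold. PLEK2 was at least 3.80-fold lower, ZNF414 at least 3.74-fold, PRSS22 at least 3.36-fold and the lysophosphatidic acid receptor LPAR2 at least 3.34-fold. ACTB and GAPDH differed by log2 -0.07 and -0.11, and both signs turned with the values as deposited, that of ACTB also under quantile normalisation.

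In all, 180 genes were at least 2-fold higher and 113 at least 2-fold lower in the combination than in control, so 38.6% of the counted genes were lower. With the values as deposited, which moved the median of all genes by 0.17 (log2), this share was 19.5%. Of the 180 higher genes 134 were dim, and of the 113 lower genes 103. Another probe set went the same way by at least 1.5-fold for 31 of the 65 higher genes that had one (47.7%) and 3 of 36 lower genes (8.33%), against 12.1% of the uncounted genes. With the stricter floor 43 genes were higher and 5 lower; 9 of the 12 named higher genes, without IFIT1, EMP1 and MATCAP2, and 1 of the 12 lower ones, GRK6, remained at 2-fold. GRK6 had a log2 difference of -0.60 as the mean of its probe sets, and TSC22D3 one of 0.00 with its gene-specific probe set, which was below the floor on both arrays.

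The named higher genes of ultrasound only against control were all among those named higher for the combination against control. TRIB1, named for the combination, was 4.11-fold higher with ultrasound only and was not among them. None of the named lower genes of ultrasound only was among those named lower for the combination. RNA45SN5 was 9.30-fold higher than in control, HSPA6 8.02-fold, KLF6 7.18-fold, TSC22D3 6.67-fold and RGS2 5.93-fold. FOSB stood at 360 and was below the floor in control, FOS was 2.24 higher on the log2 scale, PPP1R15A 2.02 and HMOX1 1.60. The lower named genes were the noncoding RNA LINC00342 (4.86-fold, with 2 other probe sets at log2 -0.23 and -0.36), KIAA1549 (3.26-fold, with 2 others at -0.31 and -0.52), the transcription factor TFAP4 (2.99-fold), SLC34A3, a sodium-phosphate transporter (2.80-fold), and the antisense RNA PITX1-AS1 (2.71-fold). The brightest of these was SLC34A3, at 288 in control.

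By group, immediate early genes had a median of 0.90 after ultrasound only, with 10 of 25 members at least 2-fold higher. Short-lived transcripts had a median of 0.48 over 23 members, MAPK phosphatases 0.41 over 17, NF-kB targets 0.31 over 18, interferon-stimulated genes 0.28 over 20, and ATF4 targets 0.22 over 21. Membrane repair genes (0.14 over 20) and ribosomal proteins (0.13 over 21) lay just above their random ranges, which ended at 0.12 for both, but as low as 0.076 and 0.026 under other processing. The interferon median was as low as 0.20 under other processing, where its range given by the main processing ended at 0.24. With gene-specific probe sets the NF-kB median was 0.13 and the ATF4 median 0.10, inside the ranges given by the brightest probe sets. G2/M genes had a median of -0.09, just below a random range that began at -0.08. JUNB, an AP-1 subunit chosen after its values were seen, stood at 458 after ultrasound only and between 224 and 237 on the other 3 arrays. In all, 215 genes were at least 2-fold higher and 94 at least 2-fold lower, of which 171 and 88 were dim. With the stricter floor 39 were higher and 3 lower.

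With Sonazoid only some of the genes above were close to control and others were not. KLF6 stood at 394 against 397 in control, TSC22D3 at 369 against 380, FOS at 84.8 against 84.9, and ANXA1 at 1949 against 2013. TRIB1 was 1.73-fold and RGS2 1.27-fold lower, each with 1 probe set above the floor. The brightest probe sets of HSPA6 and RNA45SN5 were lower (log2 -0.73 and -0.51) and their other ones higher (0.55 and 0.38). MATCAP2 was 1.59-fold, IFIT1 1.43-fold and KLF4 1.39-fold higher. The named higher genes were all dim: CASTOR2 (3.87-fold), KRABD3 (2.95-fold), PPP1R26 (2.92-fold), the kinesin light chain KLC4 (2.85-fold) and CILP2 (2.69-fold). Another probe set of CILP2 was at the floor in control and higher by at least log2 0.13. The lower ones were SLC34A3 (6.17-fold, 288 and 46.6), FAXDC2 (4.66-fold), LINC00342 (4.47-fold, with 2 other probe sets at log2 -0.17 and -0.26), RRN3P3 (3.06-fold) and LOC100652768 (2.81-fold).

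Among the groups, metallothioneins, the zinc-binding proteins, had a median of -0.22 over 7 members against a random range of -0.13 to 0.04, with MT1E at -0.22, MT1X at -0.18 and MT2A at -0.14. SRF and actin targets (-0.12 over 15) and ribosomal proteins (-0.12 over 21) were the other lists outside their range, and the immediate early median was 0.00. Under quantile normalisation the ribosomal protein median was -0.0046 and the SRF median -0.053, and that of the metallothioneins was -0.19. With the values as deposited the medians were -0.024 for ribosomal proteins, -0.032 for SRF targets and -0.13 for metallothioneins. Leaving out the scaling moved the median of all genes by 0.088 (log2), so these values cannot be placed in the random ranges of the scaled values. In all, 84 genes were at least 2-fold higher and 92 at least 2-fold lower, and 83 and 89 of them were dim, so 52.3% of the counted genes were lower, against 37.0% with the values as deposited. Another probe set went the same way for 0 of 16 higher and 4 of 25 lower genes, and with the stricter floor 0 genes were higher and 1 lower.

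The combination against Sonazoid only gives the difference with ultrasound when microbubbles were present. RNA45SN5 was 15.3-fold higher (log2 3.93, with another probe set at 3.13), HSPA6 14.4-fold (3.85, with another at 2.71), TRIB1 11.8-fold, RGS2 7.70-fold and KLF6 7.54-fold (2.91, with 4 others from at least 0.86 to 3.39). CASTOR2 (3.77-fold), GRK6 (3.56-fold, with 3 other probe sets between log2 -0.50 and -0.43), GTF2IP12 (3.32-fold), CDR2L (3.14-fold) and the nicotinic receptor subunit CHRNB2 (2.80-fold) were lower. Immediate early genes had a median of 1.07, with 13 of 25 members at least 2-fold higher. NF-kB targets (0.40 over 19), short-lived transcripts (0.33 over 21), metallothioneins (0.23 over 7), MAPK phosphatases (0.21 over 16), pro-apoptotic genes (0.15 over 23), membrane repair genes (0.12 over 19) and the unfolded protein response (0.09 over 17, and 0.058 under quantile normalisation) were above their random ranges. Of these, metallothioneins (0.12), pro-apoptotic genes (0.03) and the unfolded protein response (0.05) lay inside their ranges with ultrasound only against control. The metallothionein median was -0.22 with Sonazoid only against control and 0.00 in the combination against control. G2/M genes (-0.18 over 26) and the 4 measured erythroid and platelet markers (-0.46) were below theirs.

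In all, 189 genes were at least 2-fold higher and 92 at least 2-fold lower than with Sonazoid only. Set against ultrasound only over control, which uses the other 2 arrays, 49 genes were at least 2-fold higher in both, where independent lists of these sizes would share 3.06, and 4 were lower in both, against 0.602. Among dim genes alone 20 were higher in both, against 5.14 expected, and 3 lower in both, against 1.38. Of the 59 genes counted in both, 53 went the same way (89.8%, 95% interval 79.2% to 96.2%). With the stricter floor 28 genes were higher in both, of 39 and 36 counted, against 0.184 expected. Across 13965 genes the 2 differences had a Pearson correlation of 0.23 and a Spearman correlation of 0.19, and with the stricter floor of 0.51 and 0.36. Genes are not independent replicates.

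**Figure D3:**
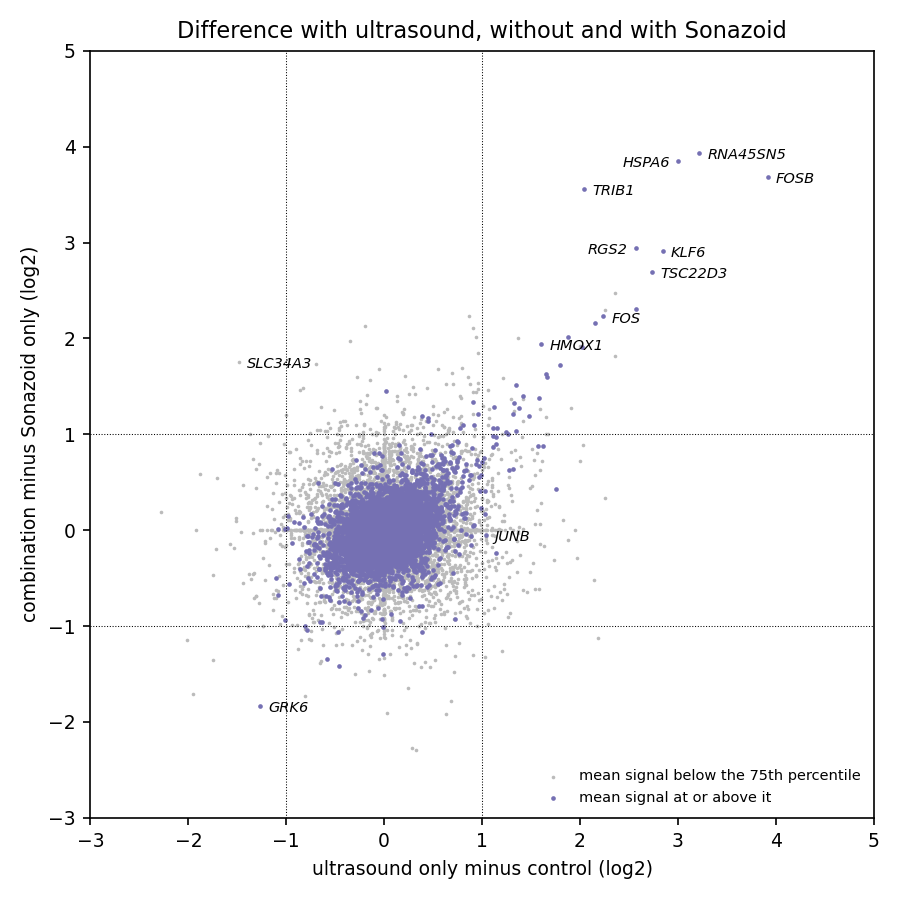
Each point is 1 gene, by its log2 difference of ultrasound only from control (x axis) and of the combination from Sonazoid only (y axis), 2 differences that share no array, with dotted lines at 2-fold. Purple points have a mean signal of 151 or more. The genes at the upper right include KLF6 at 2.84 and 2.91 and HSPA6 at 3.00 and 3.85, and JUNB lies to the right near 0 on the y axis.

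The combination against ultrasound only gives the difference that Sonazoid made under ultrasound. Among genes named higher for the combination against control, KLF6 differed by log2 0.06, FOS by -0.01, HSPA6 by 0.11 and RGS2 by 0.04. TRIB1 was higher by 0.73 (326 and 539). Other genes named in earlier comparisons, such as DEFB124, PITX1-AS1 and CACNG4, differed more, as given next. The named higher genes were UBBP2 (4.17-fold), DEFB124 (3.85-fold), PITX1-AS1 (3.41-fold), APOL2 (2.57-fold) and ADM5 (2.53-fold), all dim. The lower ones were CACNG4 (4.63-fold), the peptide hormone gene ADM2 (3.79-fold), the transcription factor FOXO4 (3.60-fold), PHETA1 (3.44-fold) and TVP23C (3.34-fold).

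By group, histones (0.25 over 11) and heat shock proteins (0.09 over 18) were above their random ranges, the latter not when HSPA6 was left out (0.068 over 17, with a range up to 0.078), and myeloid progenitor markers (-0.25 over 13) below. Ribosomal proteins (-0.18 over 21) and short-lived transcripts (-0.14 over 22) were also below, and both were positive with the values as deposited. Under quantile normalisation the ribosomal protein median was -0.025 and under median scaling the short-lived one -0.099, both inside the ranges given by trimmed-mean scaling. No ranges were computed for those 2 scalings. The myeloid median was -0.037 with the values as deposited, which moved the median of all genes up as well, so it cannot be placed in that range. In all, 92 genes were at least 2-fold higher and 152 at least 2-fold lower, with 90 and 149 of them dim. The share that was lower was 62.3%, and 27.8% with the values as deposited, which moved the median of all genes by 0.21 (log2). With the stricter floor 2 genes were higher and 0 lower. Against Sonazoid only over control, 7 genes were higher in both and 7 lower in both. Among dim genes, which held all 7 and 6 of these, independent lists would share 1.49 and 2.42. Of the 19 genes counted in both, 14 went the same way (73.7%, 95% interval 48.8% to 90.9%), and the correlation across genes was 0.07 (Pearson) and 0.10 (Spearman).

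Departure from additivity asks whether the combination differed from the sum of the separate differences. Of the 5 highest genes with ultrasound only, KLF6 departed by log2 0.07, TSC22D3 by -0.05, RGS2 by 0.38 and RNA45SN5 by 0.72, and FOS departed by -0.01. HSPA6, the other of the 5, departed by 0.85 and TRIB1 by 1.52. Other probe sets departed by -0.50 for HSPA6, -0.32 for RNA45SN5, 0.31 for TSC22D3 and between -0.48 and 0.54 for KLF6, so the signs of these departures depend on the probe set. The other probe set of TRIB1 was above the floor on the ultrasound only array alone, so it cannot measure the departure of TRIB1. The largest named departures were dim genes. Above additivity were SLC34A3 (9.43-fold), LINC00342 (5.52-fold, with other probe sets at log2 2.36 and 0.39), RRN3P3 (5.38-fold), the calcium-binding protein NECAB2 (4.60-fold) and UBBP2 (3.84-fold). Below it were CASTOR2 (5.83-fold), CILP2 (5.53-fold), PHETA1 (4.62-fold), CHRNB2 (4.57-fold) and LDAF1, a lipid droplet protein (4.51-fold). RRN3P3 and CILP2 each had another probe set above the floor on 1 array only, which cannot measure a departure. The brightest LINC00342 probe set differed from control by log2 -1.97 in the combination, -2.28 with ultrasound only and -2.16 with Sonazoid only. Those differences and its departure share the 1 control array, while the probe set at 2.36 stood 1.96 above control in the combination. Histones had a median departure of 0.38 over 11 members, and myeloid progenitor markers (-0.12 over 15) and erythroid and platelet markers (-0.68 over 5) lay below their random ranges. Under median scaling the myeloid median was -0.081, but that scaling also moved the median of all genes by 0.037, and no range was computed for it.

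In all, 284 genes lay at least 2-fold above additivity and 336 at least 2-fold below, 274 and 320 of them dim. The share below was 54.2%, and 40.8% with the values as deposited, which moved the median of all genes by 0.11 (log2). Of the 214 counted genes with another probe set above the floor on at least 1 array, 40 had one that departed at least 1.5-fold the same way. For 43 one departed the opposite way. With the stricter floor 7 genes lay above and 5 below.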

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

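The tests on ribosomal RNA probe sets and on the heat shock response were chosen only after the result was seen; the 3 tests on dim genes were written before theirs, but setting the overlap of dim genes beside the Sonazoid share came after.

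Some control probe sets of the array, which enter none of the comparisons of genes, were at least 2-fold brighter in treated cells than in control cells. The middle part of 28S ribosomal RNA (28S M) was 4.02-fold higher in the combination and 3.72-fold with ultrasound only. The 5' part (28S 5') was 47.1-fold and 5.60-fold higher, and the 3' part (28S 3') 2.06-fold higher with ultrasound only and at 0.912-fold in the combination. The 28S 5' signal in the combination (16854) was near the top of the range, like those of ACTB and GAPDH, so the size of that difference is uncertain. With Sonazoid only 28S M was 1.96-fold and 28S 5' 1.58-fold of control. The poly(A) spike-in probe set LysX-5 was 2.03-fold higher in the combination and r2-Bs-lys-3 was 2.11-fold higher with ultrasound only.

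In all, 6 genes, all of them dim, were at least 2-fold different with ultrasound in opposite directions without and with Sonazoid. Those of them named by the rule and above the floor on all 4 arrays were CILP2 (log2 1.20 without and -1.26 with), NECAB2 (-1.0 and 1.20) and SLC34A3 (-1.48 and 1.75). Each side rests on 1 array per group, and the difference between them was not tested. The number of opposite genes expected of independent lists was not computed, so the 6 cannot be read as more than chance.

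Most genes counted at 2-fold were dim, and noise of dim probe sets was weighed as their source. After ultrasound, 23 of the dim genes counted both without and with Sonazoid went the same way and 6 opposite ways. The same-way share was 79.3% (95% interval 60.3% to 92.0%), which argues against noise as the whole source of these genes. Among dim genes measured in both differences, 157 were higher and 80 lower without Sonazoid, and 144 and 76 with it. Most of them were counted in only 1 of the 2 differences, and the share does not speak to those. After Sonazoid 13 went the same way and 5 opposite ways, a share of 72.2% (46.5% to 90.3%). That interval includes an even split, which the rule written in advance reads as noise. That reading was changed after the share was seen. Among these dim genes 7 were higher in both against 1.49 expected of independent lists and 6 lower against 2.42, so noise is neither shown nor excluded. Among genes departing from additivity, other probe sets went the same way in 48.2% of the cases where they took a side (37.1% to 59.4%). The rule written in advance reads this as noise. Probe sets above the floor on only 1 array were included, and these cannot measure a departure, so the share does not decide. A response to Sonazoid too small for these arrays stays open.

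Ribosomal RNA probe sets of the 45S precursor, 28S M and 28S 5' were brighter after ultrasound, and RNA45SN5 stood at 296 in control, 2749 with ultrasound only and 3181 in the combination. Degraded messenger RNA stays open. The 3' to 5' ratio of ISGF3A was higher than in control by 0.51 (log2) with ultrasound only and by 0.13 in the combination, with a dim 5' end, and the ACTB and GAPDH probe sets were too near the top of the range to decide. More RNA without poly(A) tails in the labelling cannot be told apart from a higher level of the precursor: the 18S probe sets had a median of -0.087 with ultrasound only and of 0.76 in the combination, and they were dim in control (69.3 to 138). With Sonazoid only they differed from control by log2 0.56, 0.62 and -0.055, so the 0.76 is not particular to ultrasound. The upper quartile of the histone list had been looked at first for this test and was replaced. For the 28S 5' probe set, higher by 3.07 in the combination than with ultrasound only, a general increase of ribosomal RNA signal is argued against by the median of 0.20 of the other ribosomal RNA probe sets, and the cause was not tested further.

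Immediate early genes were higher after ultrasound, with FOSB, KLF6 and FOS far above control, and a heat shock response was weighed as the source. The heat shock list had an upper quartile of at most 0.30 (log2) in the arrays with ultrasound, while HSPA6 was 8.67-fold higher in the combination and 8.02-fold with ultrasound only. HSPA1A and HSPA1B, 2 main members of that response, share their probe sets and were not used here, so a heat shock response stays open. A response to the mechanical or chemical effects of ultrasound stays open, and so does any difference in handling between the single cultures; neither was tested.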

How the results depend on the processing

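The floor at the 75th percentile and the values as deposited were chosen only after seeing the data; all other alternatives were planned. No paired analysis was possible because the groups share only 1 replicate number; the differences with ultrasound, without and with Sonazoid, were set side by side instead. The counts below are given as higher and lower for, in this order, the combination against control, ultrasound only against control, Sonazoid only against control, the combination against ultrasound only, the combination against Sonazoid only, and as above and below for the departure from additivity. Signal over background limits the counts, since a higher floor removes the dim genes by construction and a larger threshold counts fewer genes.

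With the floor at the 40th percentile the counts were 476 and 363, 538 and 325, 321 and 363, 385 and 480, 486 and 349, and 758 and 822. The correlation of the differences with ultrasound, without and with Sonazoid, was 0.13. With the floor at the 60th percentile they were 90 and 29, 107 and 24, 19 and 27, 19 and 37, 85 and 26, and 88 and 115, with a correlation of 0.35. With the floor at the 75th percentile they were 43 and 5, 39 and 3, 0 and 1, 2 and 0, 36 and 3, and 7 and 5. The correlation was then 0.51 for ultrasound and 0.20 for Sonazoid. At a threshold of 1.5-fold the counts were 761 and 605, 880 and 525, 510 and 552, 574 and 773, 756 and 564, and 982 and 1152. At 3-fold they were 30 and 12, 43 and 9, 5 and 12, 10 and 18, 36 and 9, and 49 and 72.

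With the mean of all probe sets 57 genes were lower in the combination than with Sonazoid only. With gene-specific probe sets the immediate early median in the combination was 0.62, and KLF2 reversed to -0.15. With the values as deposited 301 genes were higher and 73 lower in the combination than in control, and 221 higher and 85 lower than with ultrasound only. The G2/M median in the combination reversed to 0.052. For the probe set choices the cause was not tested; for the values as deposited it is the missing scaling factor.

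Scaling to equal medians and quantile normalisation moved none of these counts by more than 1.5 times. The immediate early median of the combination stayed between 0.62 and 1.08 in all settings. A list median or a named gene is called the same here when it moved by no more than 1 robust SD of all genes in that comparison (0.209 to 0.310 on the log2 scale), a wide tolerance for a list. It is called reversed only when a list outside its random range, or a gene at 2-fold or more, turned sign. Of 508 values of list medians, in the combination and ultrasound only against control, 495 were the same, 12 moved and 1 reversed. Of 1663 values of named genes 1342 were the same, 320 moved and 1 reversed. Signs near 0 turned more often: under at least 1 of the 3 other scalings 13 of 29 list medians and 10 of 163 named genes did so in the combination against control. For list medians it was 7 of 30 with ultrasound only and 21 of 30 with Sonazoid only against control, 17 of 30 for the combination against ultrasound only, 5 of 30 against Sonazoid only, and 12 of 30 for the departure. The histone median in the combination lay between 0.0044 and 0.48, the short-lived one between 0.23 and 0.75 there and between 0.33 and 0.75 with ultrasound only.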

Other observations

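The tests of FOXO targets and of cAMP and CREB targets were chosen only after the result was seen, and so was the stricter floor.

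Genes outside the lists and the ranked genes also stood higher with ultrasound both without and with Sonazoid. They were picked as members of the 28 genes at least 2-fold higher in both with the stricter floor, after their values were seen. Among them were vimentin (VIM, log2 1.58 without and 1.38 with Sonazoid), lamin A/C (LMNA, 1.48 and 1.19), the annexin partner S100A10 (1.27 and 1.00), MYADM (1.15 and 1.06), CRIP1 (1.38 and 1.27), and TNFRSF12A, the TWEAK receptor (1.35 and 1.04). The aryl hydrocarbon receptor AHR (1.34 and 1.51) and TIPARP, a target that limits it (1.12 and 1.07), were both higher, as were the cell cycle regulator RGCC (1.42 and 1.40) and the trafficking protein RAB11FIP1 (1.24 and 1.02). The others were ANXA1, DDIT4, FCAR, FOS, FOSB, HMOX1, HSPA6, JUN, KLF4, KLF6, MCL1, PHLDA1, PPP1R15A, RGS2, RNA45SN5, SGK1, TRIB1 and TSC22D3.

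The poly(A) spike-in controls, added before labelling, had a median of 1.56-fold in the combination against control, 1.23-fold with ultrasound only and 1.36-fold with Sonazoid only. The hybridisation controls had median log2 differences of -0.18, -0.10 and -0.35. In the combination 23 of the 24 poly(A) probe sets lay above control. Their median of 0.64 (log2) was farther from 0 than that of the NF-kB targets there (0.29). Scaling to these controls was not tried, so the counts and signs it would give are not known.

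KLF6, TSC22D3 and DDIT4 are FOXO targets, and a FOXO response was tested as a hypothesis. A list of such targets had a median of 0.017 with ultrasound only against control, inside the random range, and 0.17 in the combination against Sonazoid only, just above its range. It was -0.18 with Sonazoid only against control, below its range, and 0.093 in the combination against control, inside it, so the arrays do not settle it. RGS2, FOS and DUSP1 are cAMP and CREB targets, and that list had a median of 0.14 without Sonazoid and -0.06 with it, both inside the random range.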
